A study of Mus musculus with 8 samples.

How the data were processed

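Transcripts of liver and kidney of Swiss albino mice were measured on Agilent 2-colour arrays with 15208 probes beside 536 control spots. Each tissue had 4 arrays, 1 for control mice and 1 each for low, intermediate and high parasitaemia, coded 0, 1, 2 and 3. Per the labels, both dyes of an array carried RNA of the same group, and nothing in the labels says that the dyes held different mice. The array was therefore the sample, the mean of its dyes was its value, and p-values measured only the spread between single arrays of different parasitaemia levels, which may be partly technical.

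Per the file headers, the scanner intensity values were extracted with Agilent Feature Extraction 10.5.1.1, which subtracted background and normalised the dyes within each array to give the processed signal, with no scaling between arrays. Per the labels, the authors also deposited log2 values of each channel, shifted to its 75th percentile. Set against the scanner values, those deposited log2 values equalled the log2 median spot signal minus the channel's 75th percentile, with no background subtraction, within 0.01 for all 15208 probes (the largest difference was 0.005 to 0.007). The median deposited log2 value of the Cy3 and Cy5 channels was -2.47 and -2.73 for kidney control, -2.33 and -2.71 for kidney low, -2.54 and -2.57 for kidney intermediate, -2.28 and -2.53 for kidney high, -0.91 and -1.77 for liver control, -1.47 and -1.69 for liver low, -1.71 and -2.28 for liver intermediate, and -1.38 and -1.99 for liver high. Probe coordinates are those in the files, on mm8. Per the file headers, the files also carried flags for spots well above background, saturated spots and outlier spots.

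For the main values, the log2 processed signal of each channel was reduced by that channel's 75th percentile, control spots were left out, and spots with an outlier flag were set to missing (93 and 105 spots in the Cy3 and Cy5 channels of the liver low array, 16 or fewer in any other channel). The accessions of 12930 probes matched the gene table used for naming, and 1368 of these took a newer symbol than the file's name. The probes covered 10715 names, of which 10515 were gene symbols, and a gene was represented by its brightest probe over all channels. Among genes with several measured probes, other probes changed at least 2-fold in the opposite direction for 4 of 774 genes at liver low, 3 of 899 at liver intermediate, 3 of 885 at liver high, 0 of 1895 at kidney low, 2 of 1881 at kidney intermediate and 2 of 1907 at kidney high. Genes well above background in both channels of at least 1 fitted array, with a value on every array, were tested.

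The tests used lmFit and eBayes of limma 3.58.1 in R 4.3.3, with version 1.17.8 of data.table, 2-sided, with Benjamini-Hochberg adjustment at 0.05. They compared the 3 infected arrays with the control array in each tissue and over both tissues with tissue as a term, the difference of that effect between tissues, and a slope per level step in each tissue. A single level against control had 1 array on each side and no test, so genes changed at least 2-fold in the same direction in both channels were counted. The figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

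Gene lists were tested with camera in limma at an inter-gene correlation of 0.01, again with an estimated correlation, and with fry. At each level, a list's median was also placed among 10000 random lists of the same size matched on mean expression. The 32 lists covered interferon-gamma response, type I interferon response, MHC antigen presentation, acute phase proteins, haem and iron handling, oxidative stress response, erythroid cells, cytochrome P450 and drug metabolism, hepatocyte secretory and metabolic genes, complement and coagulation, fatty acid oxidation and ketogenesis, cholesterol and fatty acid synthesis, gluconeogenesis with fasting and glucocorticoid response, cell cycle, inflammatory cytokines and chemokines, apoptosis and p53, unfolded protein response, hypoxia and glycolysis, circadian clock, T and NK cells, B and plasma cells, macrophages and Kupffer cells, neutrophils, endothelial cells, stromal cells and matrix, proximal tubule, distal nephron with collecting duct and glomerulus, kidney injury, ribosomal proteins, oxidative phosphorylation, male-biased mouse liver genes with Y-linked genes, and female-biased mouse liver genes with Xist. A member that was not well above background on the control array was given as at least N-fold higher, against the higher of its own value and the lowest signal among probes well above background. Ccl4, Cd274, Cd3d, Cdkn1a, Cyp17a1, Hmgb2, Ifng, Itgax and Plk1 in liver and Lcn2 and Racgap1 in kidney were near background in 1 channel of the control array, and Hao2 in 1 channel of the liver high array, so their folds are less certain.

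The groups, tests, gene lists, most alternatives and the rule for named genes were chosen before the data were examined. The rule took, per tissue and direction, the 12 genes with the largest mean change among those passing the test, filled where fewer passed with genes changed at least 2-fold in both channels at all 3 levels, ranked by their smallest absolute change. It took 5 genes per direction at each level, ranked by the smaller of the changes in the 2 channels, and 4 members per list with the largest absolute mean change. Only gene symbols well above background in both channels of every array compared were ranked for single genes. Alb, Ttr, Apoa1, Umod and Slc34a1 were read on every array as a check of the tissue labels. Kap was on the same list and was not analysed here. Some genes that the rule selected are not reported here.

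Precision was limited by 1 array per group. The 75th percentile of the raw signal lay 5.62 to 10.63 times above local background in the liver channels and 18.02 to 28.35 times in the kidney channels, and 38.2 to 58.0% of probes were well above background in liver channels against 64.8 to 73.1% in kidney channels. The r between the dyes of an array across genes, which are not independent replicates, was 0.984 to 0.996. All liver arrays lay on slide 1 and were scanned on day 1, and all kidney arrays lay on slide 2 and were scanned on day 2, so tissue and slide cannot be told apart.

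The tests were tried on simulated data with the spread found in each tissue. That spread was what the infected-against-control fit left over. It therefore includes real differences between parasitaemia levels and, in liver, the dim region of the low array. With 50 simulated genes per fold size among 6088 genes, the liver test called 0% of 4-fold, 8.0% of 8-fold and 56.0% of 16-fold changes. Among 8024 genes in kidney it called 24.0%, 84.0% and 96.0%. In the trend tests, 4.0% of 16-fold changes were called in liver and 90.0% in kidney. Over 8102 genes of both tissues the joint test called 68.0% of 4-fold changes, and the test of the tissue difference called 54.0% of 16-fold changes. In simulated lists, camera called 9 of 10 lists shifted by 1 log2 and 0 of 13 unshifted lists in liver, and 10 of 10 and 1 of 13 in kidney. With an estimated correlation none of the shifted lists was called in either tissue, and fry called 0 in liver and 10 in kidney. Noise was drawn for each gene independently. In the data the estimated correlation reached 0.78 for erythroid genes in liver and 0.92 for neutrophil genes in kidney. The simulation therefore cannot show how often camera calls unchanged lists of correlated genes, nor how many changed ones the other tests miss.

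The alternatives were the channel median in place of the 75th percentile, normexp with an offset of 50 followed by loess and Aquantile, quantile normalisation, the deposited values, no filter or a stricter filter on dim probes, the mean over the probes of a gene, either dye alone, channels as samples with dye as a term, eBayes with an intensity trend, a fit of all 8 arrays, other fold limits, and each array left out in turn. The normexp values started from median spot signals, since mean spot signals were not used here. After the data were seen, 4 alternatives were added. They left out a dim region of the liver low array (spots whose running median difference from the other 3 liver arrays, within 8 spot lines and 2 columns on each side, was below -0.5 log2), left out 486 genes typical of other tissues from the kidney fits, set the low array in place of the control array, and set the parasitaemia level as a block in the test of the tissue difference. One definition of the dim region was tried. Liver-type genes were those at least 8 times brighter on the liver control array than the mean of the kidney arrays, and the markers of pancreas, adrenal gland, brown fat, muscle and red cell precursors were listed after the arrays had been seen. The kidney mean included the infected arrays, so a gene that fell there was left out more readily than one that rose.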

Results

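The study compared transcript levels in liver and kidney of mice infected with Plasmodium vinckei, a rodent malaria parasite, with those of control mice. The infected mice were grouped by low, intermediate or high parasitaemia, which the labels tie to differing incubation of the parasite and for which percentages are not used here. There were 8 arrays, 1 per tissue and level, and no group had replicates. Changes are log2 differences from the control array of the same tissue, and the SE of a mean change comes from the fit of 3 infected arrays against 1 control array.

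The liver arrays carried liver transcripts and the kidney arrays kidney transcripts. Alb, which encodes serum albumin, read 7.47, 6.92, 6.55 and 6.83 on the liver arrays from control to high (log2 above the 75th percentile), and Apoa1, an apolipoprotein of hepatocytes, read 7.21, 7.09, 6.48 and 6.48. Ttr, the transthyretin gene of hepatocytes, read 1.51, 1.39, -0.11 and -1.22 in liver. Umod, the uromodulin gene of the thick ascending limb, read 5.79, 6.19, 6.30 and 5.95 on the kidney arrays, and Slc34a1, the phosphate transporter of the proximal tubule, read 5.39, 5.80, 5.04 and 5.29. Neither kidney gene was well above background in both channels of any liver array. Liver transcripts also appeared on part of the kidney arrays: Alb read 5.07 on the control and 4.30 on the low array, against -2.75 and -2.83 on the intermediate and high arrays. Across genes, the liver intermediate and high arrays correlated at r = 0.976 and all other liver pairs at 0.852 to 0.893, while kidney control and low correlated at 0.984, intermediate and high at 0.986, and pairs across these at 0.952 to 0.964.

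The comparison of infected with control liver asked which transcripts differed at all 3 levels together. The chemokine gene Ccl2, the granzyme gene Gzmb and the haem-degrading Hmox1 were higher on every infected liver array, and the P450 gene Cyp2c37 was lower. Ccl2, a chemokine that recruits monocytes (probe on chromosome 11, 81853343 to 81853402, mm8), was 21.9-fold higher on average (log2 change 4.46 ± 0.59 SE). Gzmb, a killing enzyme of cytotoxic T and NK cells (chromosome 14, 55213150 to 55213209), was 21.4-fold higher (4.42 ± 0.83), and Hmox1, the inducible enzyme that breaks down haem (chromosome 8, 77996380 to 77996439), was 12.4-fold higher (3.64 ± 0.77). Cyp2c37, a drug- and lipid-metabolising P450 of hepatocytes (chromosome 19, 40065288 to 40065347), was 12.7-fold lower (-3.66 ± 0.78).

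The other higher liver genes named by the rule were Serpina3g, a serine protease inhibitor of activated leukocytes (17.7-fold), Pou2af1, a transcriptional coactivator of B cells (13.5-fold), Lgals3, a galectin of macrophages (13.4-fold), Gng2, a G protein subunit (12.7-fold), Sec61a1, a subunit of the endoplasmic reticulum translocation channel (log2 change 3.39), Traf1, an adaptor of tumour necrosis factor receptors (9.4-fold), and Socs1, a feedback inhibitor of cytokine signalling (9.3-fold). Further ones were Saa1, an acute phase protein (7.6-fold), and Ralgds, an exchange factor for Ral GTPases (7.2-fold). Lower genes were Ugt2b1, a glucuronosyltransferase (10.3-fold), Lect2, a protein secreted by hepatocytes (8.8-fold), Adra1b, an adrenergic receptor (8.0-fold), Pecr, a peroxisomal reductase (7.4-fold), and the P450 genes Cyp3a11 (7.3-fold), Cyp2c39 and Cyp3a16 (7.0-fold each). Igfbp4, a binding protein of insulin-like growth factors (6.6-fold), was also lower, with Glyat, a glycine acyltransferase (5.3-fold), Sptbn4, a spectrin (4.8-fold), and Gjb1, a gap junction protein of hepatocytes (4.7-fold). The low-array spots of all these lower genes except Glyat, Cyp3a11, Gjb1 and Sptbn4, and also that of Cyp2c37, lay in a dim region that covered 25.9% of the spots of the liver low array. Scaled on the spots outside the region, the values there fell by 0.41 (Cy3) and 0.40 (Cy5) log2. Changes and list medians given for the liver low array carry this uncertainty. Of 6094 genes above background on at least 1 liver array, 400 were higher and 228 lower by at least 2-fold at all 3 levels, and the low-array spots of 31 and 137 of them lay in that region. Of the same genes, 206 higher and 114 lower ones were above background on all 4 arrays.

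None of these genes passed the test. Limma called 0 of 5999 liver genes (smallest adjusted p = 0.32), and 668 had an unadjusted p under 0.05, 464 of them higher and 204 lower, where 300 would be expected by chance. The adjusted p of Lect2 was 0.34 and that of the other named liver genes was 0.32. Without the liver low array 1656 genes passed (853 higher, 803 lower), among them all 12 named higher and all 12 named lower genes, without the liver high array 5 passed (2 higher, 3 lower), and without the liver intermediate array 0 passed. Those fits set 2 infected arrays against the lone control array, which is assumed to vary like them. The named genes were chosen for their change on all 3 infected arrays, so their passing is no independent check. The same holds for the named kidney genes below.

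Markers and mediators of immune cells were higher in the infected livers as groups, with camera calling each of these lists and none holding with an estimated correlation. The T and NK cell list had a median log2 change of 2.66 over 33 genes (camera adjusted p = 4.54e-12, adjusted p = 0.56 with an estimated correlation), with 30 members higher. Cd3d, part of the T cell receptor complex, was 20.3-fold higher, with its low-array spot in the dim region, and Ifng, the interferon-gamma gene, 16.5-fold higher. Inflammatory cytokines and chemokines had a median of 1.67 over 38 genes (2.20e-10, adjusted p = 0.56 with an estimated correlation), with Ccl4 at 21.7-fold and Ccl7 at least 12-fold higher. The interferon-gamma response had a median of 1.3 with all 20 members higher (1.49e-07, adjusted p = 0.56 with an estimated correlation), led by Socs1 at 9.3-fold, Cd274, the inhibitory ligand PD-L1, at 7.8-fold and Gbp2, a guanylate-binding GTPase, at 7.5-fold. Neutrophil genes had a median of 1.89 (1.78e-06), B and plasma cell genes 1.47 (5.06e-05), macrophage and Kupffer cell genes 0.86 (2.11e-04) and MHC antigen presentation genes 0.77 (0.0029), with an adjusted p of 0.56 with an estimated correlation for each. Without the dim region of the liver low array, the MHC median was 0.49 (adjusted p = 0.0101). Lcn2, an iron-binding lipocalin on both the neutrophil and the acute phase list, was 17.4-fold higher, and Jchain, which joins immunoglobulin units, 9.7-fold higher. Itgax, an integrin of dendritic cells and macrophages, was 11.9-fold higher, and H2-DMb1, a chaperone of MHC class II, 6.0-fold higher. Clec4f, a receptor of Kupffer cells, went the other way and was 4.9-fold lower. With members that were dim on the control array set to their bounds, the medians were 2.34 for T and NK cell, 1.55 for cytokine, 1.32 for neutrophil, 1.46 for B and plasma cell and 0.81 for macrophage genes. Adjusted over the list alone, 17 T and NK cell genes, 17 cytokine genes, 6 interferon-gamma response genes, 4 B and plasma cell genes and 0 of the other lists of this paragraph passed, against 0 over all genes.

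Cell cycle genes, which drive DNA replication and mitosis, were higher in the infected livers, with a median of 1.82 and 42 of 44 members higher (camera adjusted p = 2.49e-16, adjusted p = 0.56 with an estimated correlation). Hmgb2, a chromatin protein of dividing cells, was 24.9-fold higher, Rrm2, a subunit of ribonucleotide reductase, at least 14.1-fold, and Plk1, a mitotic kinase, 10.9-fold. Adjusted over the list alone, 18 cell cycle genes passed, against 0 over all genes. Hypoxia and glycolysis genes had a median of 1.07 (1.96e-04, adjusted p = 0.59 with an estimated correlation), with 2 passing adjusted over the list alone, and Hk2, a hexokinase, was 8.9-fold higher. Without the dim region of the liver low array their median was 1.80 over 17 in place of 21 genes (adjusted p = 0.0011). Erythroid genes had a median of 1.44 over 24 genes (0.0175, adjusted p = 0.72 with an estimated correlation). Their medians by level were -0.19, 1.91 and 2.72. Hemgn, a nuclear protein of red cell precursors, was at least 8.3-fold higher and Gfi1b, a transcription factor of the same cells, at least 4.7-fold higher. With dim members at their bounds, the medians of cell cycle and erythroid genes were 1.73 and 1.03.

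Genes of hepatocyte metabolism were lower in the infected livers. The cytochrome P450 and drug metabolism list had a median of -1.33 with 52 of 60 members lower (camera adjusted p = 5.26e-08, adjusted p = 0.56 with an estimated correlation). Its medians were -0.22, -1.64 and -2.06 from low to high. Cyp17a1, a steroid-synthesising P450, went against the list and was 26.2-fold higher. Cholesterol and fatty acid synthesis genes had a median of -1.39, or -1.3 with dim members at their bounds (2.41e-06, adjusted p = 0.56 with an estimated correlation), with Hmgcs1, an enzyme of cholesterol synthesis, 6.3-fold lower. Hepatocyte secretory and metabolic genes had a median of -0.64 (9.64e-04, adjusted p = 0.59 with an estimated correlation), with Igfals, a carrier subunit of insulin-like growth factors, 10.9-fold lower and Abcb11, the bile salt export pump, 5.4-fold lower. Female-biased liver genes had a median of -1.87 (0.0012) and male-biased liver genes -1.54 over 5 genes (0.0029), with an adjusted p of 0.56 with an estimated correlation for each. Hsd3b5, a steroid dehydrogenase higher in male mouse liver, was at least 22.8-fold lower. Oxidative phosphorylation genes had a median of -0.47 (0.0022, adjusted p = 0.61 with an estimated correlation), and the low-array spots of 17 of its 62 genes, among them Ndufb4 and Ndufs3, lay in the dim region. Gluconeogenesis, fasting and glucocorticoid genes had a median of 0.66 (0.0026, adjusted p = 0.56 with an estimated correlation), with Cdkn1a, a cell cycle inhibitor, 20.2-fold higher and Pdk4, which blocks pyruvate oxidation, 18.6-fold higher. Adjusted over the list alone, 1 male-biased gene passed, and in the other lists of this paragraph 0 passed, as over all genes.

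Other called liver lists held genes shared with those above. The kidney injury list had a median of 1.11 (camera adjusted p = 4.15e-04), stromal cells and matrix 0.95, or 0.73 with dim members at their bounds (7.82e-04), endothelial cells 0.69, or 0.53 at the bounds (0.0121) and proximal tubule genes, many of which hepatocytes also express, -0.55 (0.0339), with an adjusted p of 0.56 with an estimated correlation for each. Plaur, the urokinase receptor, was at least 11.4-fold higher, Timp1, a protease inhibitor of injured tissue, 4.1-fold higher, Icam2, an endothelial adhesion protein, 4.7-fold higher, and Hao2, a peroxisomal oxidase, 24.9-fold lower. Adjusted over the list alone, 1 kidney injury gene and 0 of the other genes of these lists passed. The proximal tubule call ended without the liver low array (adjusted p = 0.1066) and without its dim region (0.2454), where the median was -0.44 over 21 in place of 27 genes. The endothelial and stromal calls ended without the liver high array (0.1280 and 0.0858).

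Lists that camera did not call in liver included several that acute infection is known to affect. Type I interferon genes had a median of 0.65 (adjusted p = 0.0801), with level medians of 1.3, 0.35 and 0.30, and Irf7, their transcription factor, was 3.3-fold higher. The size of the low median depends on the scaling of the liver low array. Acute phase proteins had a median of 0.36 (0.0665), apoptosis and p53 genes 0.53 (0.0761), fatty acid oxidation genes -0.34 (0.1180), and haem and iron genes -0.22 (0.5312). Complement and coagulation genes had a median of -0.48 (0.1124), although F13a1, a subunit of clotting factor XIII, was at least 12-fold higher. Circadian clock genes had a median of -0.04 (0.5312), with Dbp, a clock-driven transcription factor, 18.5-fold lower. The median, mean and test differed in sign for oxidative stress genes (median -0.18, mean 0.11, adjusted p = 0.8757), unfolded protein response genes (-0.11 and 0.04, 0.5373), ribosomal protein genes (0.07 and -0.07, 0.8976) and the 3 measured genes of the distal nephron list (-0.05 and 0.36, 0.8757). The median change over all tested liver genes was -0.10, and 0.16 when channels were centred on their median, so list medians this near 0 have no settled sign.

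Single parasitaemia levels were set against control to show where transcripts differed in size. In liver, Ccl2 was 19.4-fold higher at low parasitaemia, followed by Serpina3g (19.1-fold), Cxcl10, an interferon-induced chemokine (12.3-fold), Socs1 (11.4-fold) and H2-Eb1, an MHC class II gene (11-fold). These folds at low parasitaemia may be too large, given the scaling of that array. At intermediate parasitaemia Slc16a3, a lactate exporter, was 57.0-fold higher, Dusp2, a phosphatase of activated immune cells, 42.2-fold, Gzmb 36.5-fold, Ccl8, a monocyte chemokine, 35.5-fold and Lcn2 27.9-fold. At high parasitaemia Pdk4 was 93.7-fold higher, Slc16a3 84.9-fold, Cidec, a lipid droplet protein, 75.5-fold, Dusp2 38.7-fold and Ccl2 32.6-fold.

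Among lower liver genes, Hao2 was 36.3-fold, Dbp 28.4-fold, Igfals 26.6-fold and Hsd3b2, a steroid dehydrogenase, 22.4-fold lower at intermediate parasitaemia. At high parasitaemia Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 68.2-fold lower, Dbp 55.2-fold, Serpina6, the corticosteroid-binding globulin, 52.2-fold and Car3, a carbonic anhydrase, 50.5-fold. At low parasitaemia the lowest were Ybx1, an RNA-binding protein (66.8-fold), Erdr1 (37.3-fold), Bccip, a cell cycle protein (35.9-fold), Rcl1, a ribosome assembly factor (24.3-fold), and Mug2, a hepatocyte protease inhibitor (21.1-fold). The spots of all 5 lay in the dim region of that array.

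The number of liver genes changed at least 2-fold in both channels was 576 higher and 795 lower of 5211 at low, 954 and 1044 of 5879 at intermediate, and 1016 and 979 of 5867 at high parasitaemia. The balance of higher and lower genes depended on the scaling and on dim probes. It was 1190 higher and 716 lower at intermediate with the channel median and 875 and 605 with normexp, while among genes above background on both arrays it was 501 and 886 at intermediate and 548 and 815 at high. In simulated data with no change, the rule counted 15.6%, 17.4% and 17.5% of genes at these levels, against 26.3%, 34.0% and 34.0% observed. The simulated spread includes differences between levels and the dim region. The simulated shares, and the simulated overlaps below, may therefore be too high for unchanged groups. The dim region held 628 of the 795 lower and 44 of the 576 higher genes at low parasitaemia. With it left out and channels scaled on the other spots, 320 genes were higher and 272 lower of 3967. Intermediate and high parasitaemia shared 796 higher and 821 lower genes, where independent lists would share 152.2 and 178.0 and unchanged groups simulated against the same control array 171.0 and 169.5. Low and intermediate shared 385 higher and 271 lower genes (71.1 and 157.1 if independent, 142.1 and 141.9 simulated), and low and high shared 348 and 253 (74.5 and 147.8, 139.6 and 139.5). These 3 overlaps covered fewer genes than the counts above, 5713, 5181 and 5168. For low and intermediate, for example, 548 and 672 genes were higher in this set. The covariance of changes across genes was 1.91 between intermediate and high (0.46 simulated), 0.86 between low and intermediate (0.43) and 0.79 between low and high (0.43), and part of each overlap may come from the shared control array. In the same order, r across genes was 0.95 (0.49 simulated), 0.51 (0.48) and 0.46 (0.48). By r, the pairs with low therefore lay near the simulated values.

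**Figure D1:**
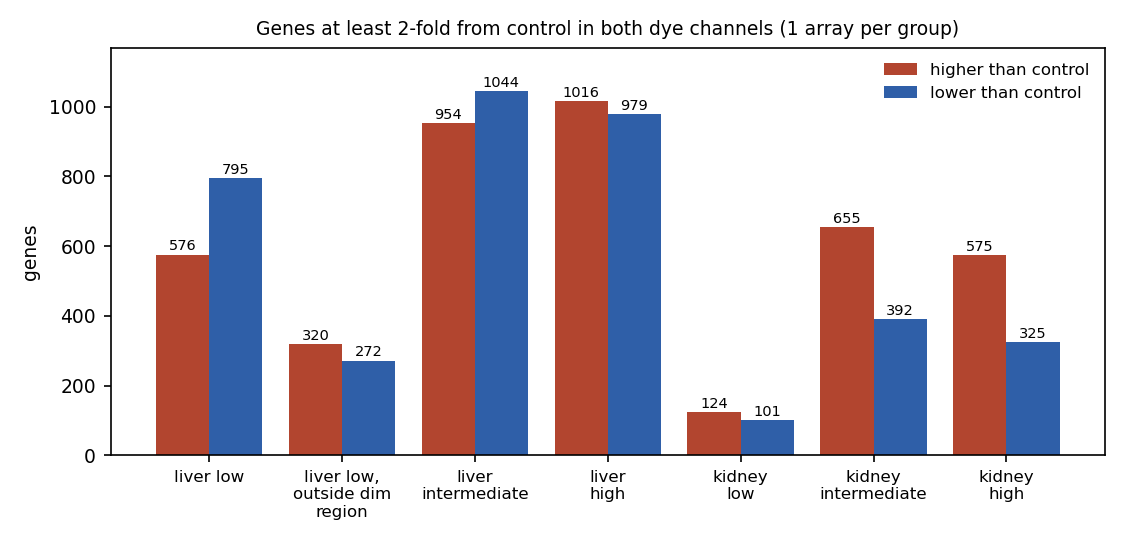
Number of genes at least 2-fold higher or lower than control in both dye channels at each parasitaemia level, in liver and kidney, with 1 array per level and with liver low also outside its dim region (320 and 272). Liver counts lie at 576 to 1016 higher and 795 to 1044 lower genes, and kidney counts go from 124 higher and 101 lower at low to 655 higher and 392 lower at intermediate parasitaemia.

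**Figure D2:**
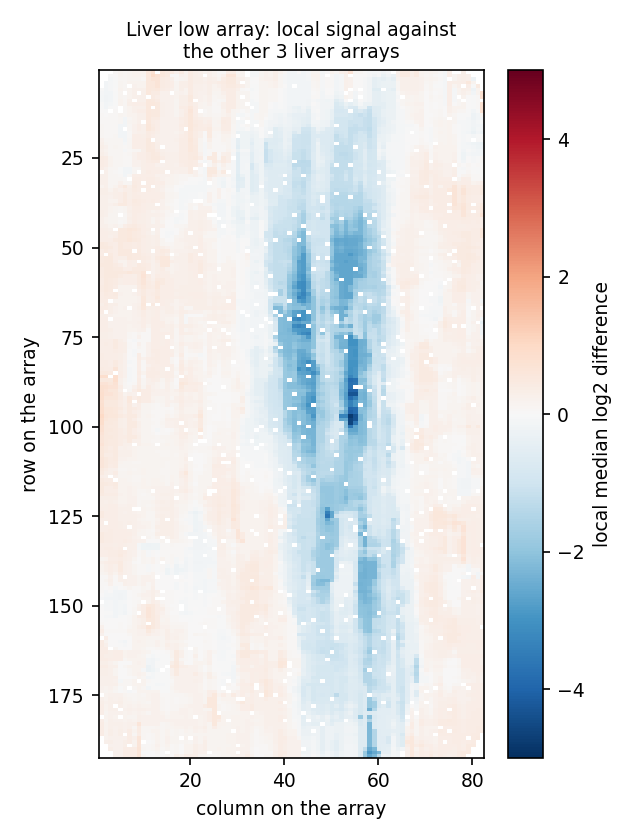
Map of the liver low array, with the column and row of each spot on the axes and the running median of the log2 difference from the other 3 liver arrays as colour. The dim region lies within columns 30 to 68 of 82 and reaches a local median of -4.80.

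The liver trend test asked which transcripts moved steadily with the level order. Limma called 0 of 5999 genes (smallest adjusted p = 0.13), with 1175 at an unadjusted p under 0.05, 618 of them with positive and 557 with negative slopes, where 300 would be expected by chance. List medians at each level were not compared by a test. Neutrophil medians were 0.78, 2.04 and 2.59 from low to high and stromal medians 0.51, 1.39 and 1.63, while T and NK cell medians were 1.75, 3.56 and 2.5 and interferon-gamma response medians 1.87, 1.72 and 1.46. Scaled on spots outside the dim region, low-array values there were lower by 0.41 (Cy3) and 0.40 (Cy5) log2. The order of the interferon-gamma response medians is therefore not settled. Without the liver control array 596 genes passed (443 with positive slopes, 153 with negative ones), without the liver high array 2, and without the low or intermediate array 0.

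**Figure D3:**
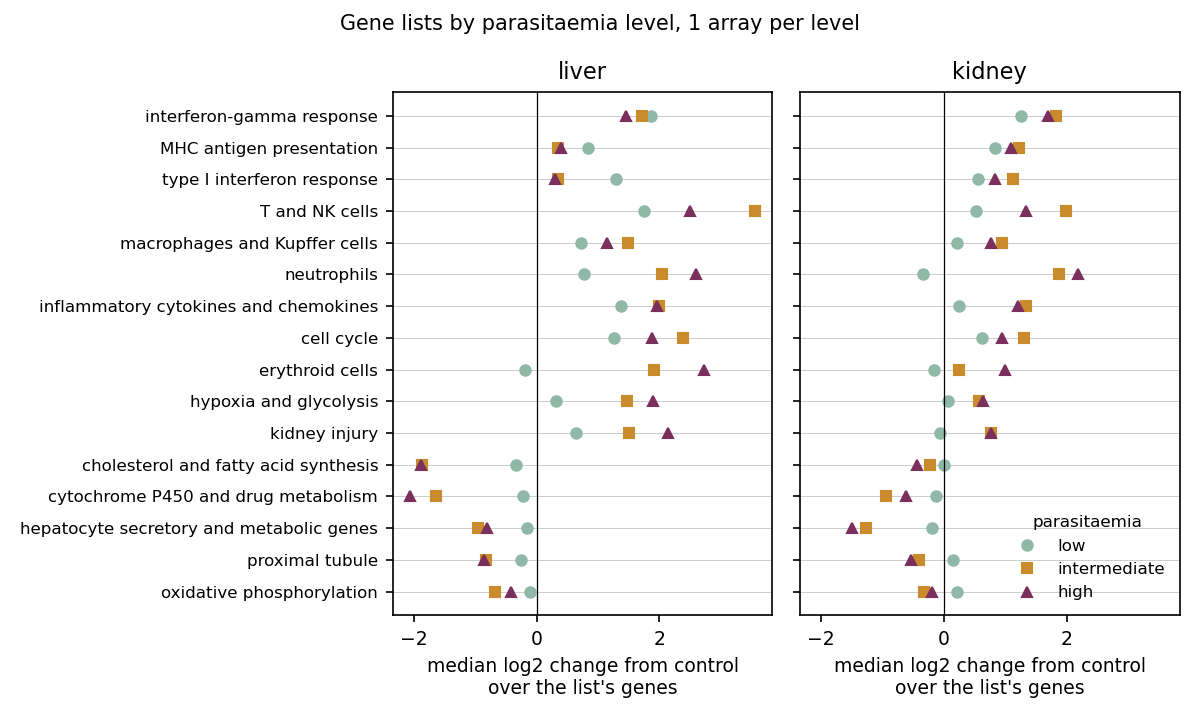
Median log2 change against control of selected gene lists at low, intermediate and high parasitaemia in liver and kidney, 1 array per level. The liver P450 list goes from -0.22 to -2.06, and the kidney interferon-gamma list lies at 1.26, 1.82 and 1.70.

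In kidney, the comparison of infected with control arrays asked the same question. The interferon-induced genes Gbp2 and Ciita and the granzyme gene Gzmb were higher on every infected kidney array. Gzmb was 20.2-fold higher on average (log2 change 4.33 ± 1.64 SE), Gbp2 (chromosome 3, 142575141 to 142575200, mm8) was 6.5-fold higher (2.70 ± 0.40), and Ciita, the master regulator of MHC class II genes (chromosome 16, 10439788 to 10439847), 4.1-fold higher (2.03 ± 0.29). Prss3, a trypsin of the pancreas (chromosome 6, 41303489 to 41303548), was 13.3-fold lower (-3.73 ± 0.32).

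The further higher kidney genes were Gbp2b, a guanylate-binding GTPase (5.8-fold), Gzma, a granzyme (5.3-fold), Cd274 (4.2-fold), Irgm1, an interferon-induced GTPase (3.4-fold), and the immunoproteasome subunits Psmb8 and Psmb9 and the cytokine inhibitor Socs1 (3.3-fold each). Tnfsf10, the death ligand TRAIL, and Nat8f5, an acetyltransferase, were 3.1-fold higher each. The further lower genes were Mbl2, a mannose-binding lectin of liver (15.1-fold), Myh8, a muscle myosin (7.6-fold), Igf2, a growth factor (6.8-fold), Cyp4f14, a P450 (4.9-fold), Npb, a neuropeptide (4.6-fold), Tlx2, a homeobox factor (3.6-fold), Marco, a macrophage scavenger receptor, and Slc24a3, a cation exchanger (3.5-fold each), Grem1, a BMP antagonist, and Hsd3b6, a steroid dehydrogenase of the adrenal cortex (3.3-fold each), and Cel, a pancreatic lipase (2.8-fold). Mbl2, Cyp4f14 and Marco were among the liver-type genes. They read 7.17, 3.51 and 4.40 on the liver control and 0.79, -0.58 and 0.53 on the kidney control array. Whether their transcripts fell in kidney cells was not tested. Markers of other tissues also differed between the kidney arrays. The median level of 15 pancreatic acinar markers, as that of Prss3 and Cel, was higher on the control array (-2.47) than on the infected arrays (-5.67, -4.79 and -4.97), and from control to high that of 13 adrenal markers was -1.84, -4.95, -1.0 and -4.29. Of 8024 genes above background on at least 1 kidney array, 73 were higher and 40 lower by at least 2-fold at all 3 levels, and 29 and 13 of them were above background on all 4 arrays.

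None of these kidney genes passed the test. Limma called 0 of 8020 genes, with 324 at an unadjusted p under 0.05 (243 higher, 81 lower) where 401 would be expected by chance. The smallest adjusted p was 0.27, which Prss3 shared with other genes. The other named kidney genes had an adjusted p of 0.50 to 0.99. Without the kidney low array 210 genes passed (103 higher, 107 lower), among them 6 of the 12 named higher genes, with Gbp2, Ciita, Gzmb, Gzma, Irgm1 and Cd274, and 7 of the 12 lower ones, and without the intermediate or high array 0 passed.

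Interferon-induced and immune cell genes were higher in the infected kidneys as groups, each by camera and none with an estimated correlation. The interferon-gamma response had a median of 1.57 with all 21 members higher (adjusted p = 4.75e-22, adjusted p = 0.65 with an estimated correlation), and 13 passed adjusted over the list alone, against 0 over all genes. MHC antigen presentation had a median of 1.06 (2.55e-15, adjusted p = 0.65 with an estimated correlation), with 7 passing adjusted over the list alone, and Tap1 and Tap2, the peptide transporters, were 3.5-fold and 3.0-fold higher. The type I interferon response had a median of 0.78 (4.57e-08, adjusted p = 0.65 with an estimated correlation), with 3 passing adjusted over the list alone, Irf7 3.8-fold higher and Zbp1, a nucleic acid sensor, 2.8-fold higher. Cell cycle genes had a median of 1.0 with 45 of 50 higher (1.25e-17), T and NK cell genes 1.34 with 35 of 37 higher (3.71e-13), and cytokines and chemokines 0.86 with 42 of 44 higher (1.77e-10), with an adjusted p of 0.65 with an estimated correlation for each. Racgap1, a cytokinesis protein, was 3.0-fold higher, Pdcd1, the checkpoint receptor PD-1, 4.8-fold higher, Ccl4 4.7-fold higher and Il10, an anti-inflammatory cytokine, at least 3.0-fold higher. Neutrophil genes had a median of 1.1 (3.07e-04), with level medians of -0.34, 1.88 and 2.18, macrophage genes 0.80 (0.0029) and B and plasma cell genes 0.30 (0.0302), with an adjusted p of 0.65 with an estimated correlation for each. With dim members at their bounds, the medians of cell cycle, T and NK cell, cytokine and neutrophil genes were 0.96, 1.31, 0.84 and 0.99. Adjusted over the list alone, 0 genes of these last 6 lists passed. The B and plasma cell call ended without the kidney intermediate array (adjusted p = 0.1074) and without the high array (0.0853).

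Hypoxia, stress and injury genes were also higher in the infected kidneys, with smaller medians and with an adjusted p of 0.65 with an estimated correlation for each list. Gluconeogenesis, fasting and glucocorticoid genes had a median of 0.62 (camera adjusted p = 6.81e-05), kidney injury genes 0.48 (0.0055), hypoxia and glycolysis genes 0.37 (9.55e-04), oxidative stress genes 0.30 (0.0029), ribosomal protein genes 0.24 (0.0010), fatty acid oxidation genes 0.23 (0.0276), and apoptosis and p53 genes 0.19 (0.0478). Hmox1 was at least 16.9-fold higher, as 1 channel was saturated at intermediate parasitaemia, with a log2 change of 0.63 at low parasitaemia. Lcn2, also a marker of tubular injury, was 13.3-fold higher, Cdkn1a 5.1-fold, Mt1, a metal-binding metallothionein, 3.0-fold, and Pdk4 3.0-fold. Epo, the hormone that drives red cell formation, was at least 2.5-fold higher. Injury markers did not all rise. Of 32 kidney injury genes, 27 were higher and 5 lower. At intermediate and at high parasitaemia, 12 were at least 2-fold higher and 2 at least 2-fold lower. Havcr1, another marker of tubular injury, was lower on every infected kidney array (-2.05, -1.87 and -2.88 from low to high) than on the control array. It was among the liver-type genes. Without the kidney low array the calls of fatty acid oxidation (adjusted p = 0.1363) and ribosomal protein genes (0.1344) ended, without the intermediate array those of fatty acid oxidation (0.1174) and apoptosis and p53 genes (0.1428), and without the high array those of apoptosis and p53 (0.0555) and kidney injury genes (0.0565).

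Tubular genes were lower over the infected kidneys by small amounts, and not at every level. Proximal tubule genes had a median of -0.28 with 45 of 54 lower (camera adjusted p = 2.99e-04), with level medians of 0.15, -0.41 and -0.53, genes of the distal nephron, collecting duct and glomerulus -0.12 (0.0436), with -0.14, -0.40 and 0.03, and cholesterol and fatty acid synthesis genes -0.11 (0.0222), with 0.01, -0.22 and -0.43, with an adjusted p of 0.65 with an estimated correlation for each. Slc22a7, an organic anion transporter, was 2.3-fold lower, Gatm, an enzyme of creatine synthesis, 2.1-fold, and Aqp2, the water channel of the collecting duct, 2.0-fold. The distal nephron call ended without the kidney low (adjusted p = 0.0711) or intermediate array (0.1803), and the cholesterol synthesis call without the high array (0.0853).

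Genes of liver function were lower on the kidney intermediate and high arrays, where the liver-type transcripts of the control and low arrays were lower as a whole. Over 437 liver-type genes the median level was -2.24 on the control, -2.32 on the low, -3.51 on the intermediate and -3.54 on the high array. Hepatocyte secretory and metabolic genes had a median change of -1.04 (camera adjusted p = 1.05e-08), female-biased liver genes -1.22 (3.14e-05) and P450 and drug metabolism genes -0.53, or -0.52 with dim members at their bounds (3.51e-05), with an adjusted p of 0.65 with an estimated correlation for each. Alb was 45.3-fold lower on average. Cyp3a41a, a female-biased P450 of liver, read 2.31 on the control and 1.78 on the low array, and -5.78 and -5.70 on the intermediate and high arrays, where 1 channel was near background. Adjusted over the list alone, 2 female-biased genes and 0 genes of the other lists of this and the preceding 2 paragraphs passed. Without liver-type genes and markers of other tissues, these 3 calls ended (adjusted p = 0.1585 for 11 hepatocyte, 0.6891 for 5 female-biased and 0.4161 for 17 P450 genes). Part of this may come from the choice of liver-type genes, which used the infected kidney arrays and so left out falling genes more readily.

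Camera did not call erythroid genes in kidney (median 0.33, adjusted p = 0.4491, level medians -0.16, 0.24 and 0.99), nor endothelial (0.27, 0.2050), stromal (0.28, or 0.25 with dim members at their bounds, 0.3088), circadian (0.10, or 0.04 at the bounds, 0.5154), oxidative phosphorylation (-0.08, 0.0998), haem and iron (-0.12, 0.2476) or male-biased genes (-0.26, 0.2965). Within the stromal list, Lox, which cross-links collagen, was 8.8-fold higher, and within the haem list Cd163, the scavenger receptor for haemoglobin, was at least 2.4-fold lower. The median, mean and test differed in sign for acute phase proteins (median 0.15, or 0.03 with dim members at their bounds, mean -0.20, adjusted p = 0.7855), complement and coagulation genes (0.02 and -0.63, 0.3088) and unfolded protein response genes (-0.06 and 0.11, 0.9859). Without genes of other tissues, the medians were 1.40 over 6 acute phase genes and 0.40 over 19 complement and coagulation genes (camera adjusted p = 0.0024 for each). The liver-type genes left out were chosen with the infected kidney arrays in the mean, which favours rising genes among those kept. These calls therefore cannot show that the lists were higher in kidney.

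Among higher kidney genes at single levels, Gbp2 was 5.3-fold and Gbp2b 4.9-fold higher at low parasitaemia, with Gng13, a G protein subunit (4.6-fold), Hamp2, a hepcidin (4.3-fold), and Ucp1, the uncoupling protein of brown fat (4.2-fold). Hmox1 was at least 64.7-fold higher at intermediate parasitaemia, where 1 channel was saturated, and 48.5-fold higher at high parasitaemia. Gzmb was 57.2-fold and 38.4-fold higher and Lox 37.6-fold and 19.9-fold higher at these levels. S100a8, a calcium-binding protein of neutrophils, was 11.9-fold and Pdcd1 10.6-fold higher at intermediate, and Aire, a regulator of tissue antigens in thymus, 20.4-fold and Gbp2b 13-fold higher at high parasitaemia.

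The lowest kidney genes were markers of other organs. At low parasitaemia Hsd3b1 (116.3-fold), Chga, a chromaffin granule protein (109.3-fold), Star, the cholesterol carrier of steroid-making cells (69.0-fold), Akr1b7, an aldose reductase of the adrenal cortex (15.7-fold), and Prss3 (13-fold) were lower. At intermediate parasitaemia the liver genes Alb (226.8-fold), Apoa2, an apolipoprotein (122.0-fold), Ahsg, fetuin-A (115.3-fold), Uox, urate oxidase (74.1-fold), and Hpx, hemopexin (55.9-fold), were lower. At high parasitaemia Alb (238.9-fold), Ahsg (168.8-fold), Hpx (86.1-fold), Apoa2 (76.9-fold) and Mup4, a major urinary protein (74.0-fold), were lower.

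Kidney genes changed at least 2-fold numbered 124 higher and 101 lower of 7693 at low, 655 and 392 of 7753 at intermediate, and 575 and 325 of 7852 at high parasitaemia. These were 2.9%, 13.5% and 11.5% of genes, against 4.7%, 4.9% and 5.4% in simulated data with no change. The simulated spread includes differences between the infected arrays. The simulated shares, and the simulated overlaps below, may therefore be too high for unchanged groups. With normexp 73, 481 and 355 of the same genes were counted and with the deposited values 90, 606 and 463, and the simulation was not run on these values. Liver-type genes made up 19 of the 101, 138 of the 392 and 130 of the 325 lower genes, and without them and markers of other tissues 112 were higher and 61 lower at low, 620 and 236 at intermediate, and 554 and 170 at high parasitaemia. The choice of liver-type genes used the infected kidney arrays, so falling genes were left out more readily than rising ones. Intermediate and high shared 388 higher and 225 lower genes (41.1 and 16.6 if independent, 59.8 and 58.8 for unchanged groups simulated against the same control array). Low and intermediate shared 67 and 48 (7.4 and 5.2, 56.5 and 56.2), and low and high 74 and 62 (6.6 and 4.3, 56.8 and 55.7). These overlaps covered fewer genes than the counts above, 7660, 7555 and 7597. For low and intermediate, for example, 99 and 567 genes were higher in this set. The covariance of changes was 0.68 between intermediate and high (0.21 simulated), 0.17 between low and intermediate and 0.19 between low and high (0.21 simulated for each), and part of each overlap may come from the shared control array. In the same order, r across genes was 0.86 (0.54 simulated), 0.38 (0.55) and 0.44 (0.54). By r and covariance, the pairs with low therefore lay below the simulated values.

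**Figure D4:**
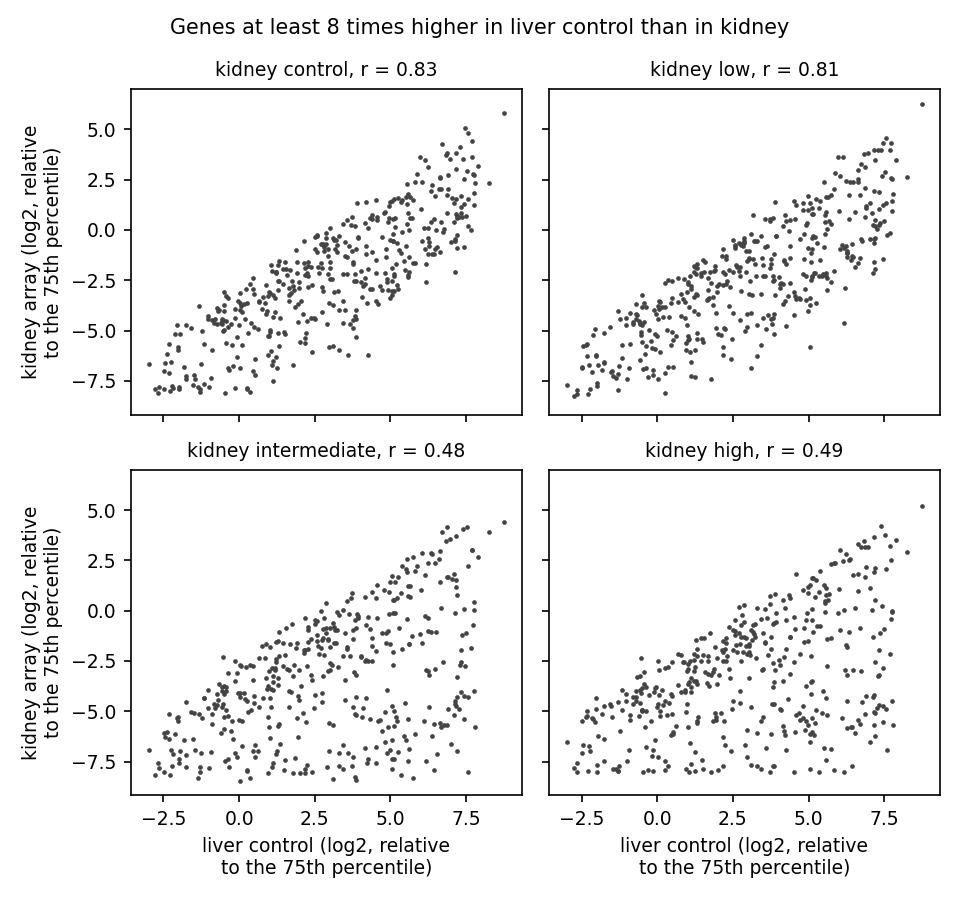
Level of 437 liver-type genes on each kidney array against their level on the liver control array (log2 above the 75th percentile, 1 point per gene). The kidney control and low arrays follow the liver levels at r = 0.83 and 0.81 across genes, the intermediate and high arrays at 0.48 and 0.49. The genes were selected on these same arrays, which can raise r.

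The kidney trend test called 0 of 8020 genes by limma (smallest adjusted p = 0.25), with 1156 at an unadjusted p under 0.05, 738 of them with positive and 418 with negative slopes, where 401 would be expected by chance. No array left out brought any gene past the threshold. From low to high, in values that no test compared, cytokine and chemokine medians were 0.24, 1.34 and 1.21, kidney injury medians -0.07, 0.76 and 0.77, and hepatocyte medians -0.20, -1.27 and -1.50.

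The last comparisons asked which responses liver and kidney shared. The 9 genes at least 2-fold higher in both channels of all infected arrays of both tissues were the granzyme genes Gzmb and Gzma, the latter with its liver low spot in the dim region, Socs1, Cd274, Irf7, Serpina3g, Batf2, a transcription factor of activated macrophages, Ccl19, a chemokine for T cells and dendritic cells, and Chtf18, a replication factor. The 3 genes lower in both were Amy2a5, a pancreatic amylase, and the P450 genes Cyp2c37 and Cyp3a16, whose liver low spots all lay in the dim region and which belong to the tissues whose markers differed between kidney arrays. No gene was higher in one tissue and lower in the other by this rule at all levels, a count with no test. Over 5912 genes, mean changes in the tissues correlated at r = 0.46 across genes, which are not independent replicates. Liver-type genes were not left out of this correlation.

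Limma over both tissues called 0 of 8009 genes (smallest adjusted p = 0.27), with 865 at an unadjusted p under 0.05 (579 higher, 286 lower) where 400 would be expected by chance. At intermediate parasitaemia liver and kidney, which have separate control arrays, shared 350 higher and 127 lower genes (83.7 and 39.5 if independent, 14.4 and 14.3 for simulated unchanged groups), and 29 genes were opposite. At high they shared 266 and 110 (66.4 and 32.2, 14.8 and 15.8), with 23 opposite, and at low 29 and 9 (4.9 and 4.8, 11.6 and 11.2), with 10 opposite. The lower genes shared at low were fewer than in the simulation, whose spread includes differences between levels. These overlaps covered fewer genes than the counts of each tissue above (5804 at intermediate and 5790 at high, with 229 and 199 lower in kidney). Among all lower kidney genes, 138 of 392 at intermediate and 130 of 325 at high were liver-type genes. Liver-type transcripts on the kidney control array may therefore account for part of the shared lower genes. How many was not counted. The test of the difference of the infection effect between liver and kidney called 0 of 8009 genes (smallest adjusted p = 0.52), with 485 at an unadjusted p under 0.05 where 400 would be expected, and 14 without the liver low array (3 larger in liver, 11 larger in kidney).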

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

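The comparison of liver with kidney was planned, and the tests of the lower genes of the liver low array and of liver-type transcripts in kidney were chosen after the results were seen.

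Ralgds, an exchange factor for Ral GTPases, stood out because it was above its control on every infected liver array and on no infected kidney array. Its changes at low, intermediate and high parasitaemia were 2.67, 2.96 and 2.92 in liver and -0.72, -0.33 and 0.00 in kidney, and its mean change was 3.20 larger in liver, with an adjusted p of 0.52 by limma for the difference.

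The lower genes of the liver low array, among them Ybx1, Bccip and Mug2, may reflect a dim region of the array. With each spot judged by neighbouring spots of other genes alone, 78.2% of the lower genes and 23.8% of the counted genes had dim neighbours, a ratio of 3.29. Lower transcript levels with low parasitaemia should have shown in other probes of the same genes outside the region, but over 80 genes these had a median change of 0.10 (quartiles -0.25 and 0.41), or -0.26 when scaled on the spots outside the region, against -1.88 for the probes inside it. Of these 80 genes, 4 were lower by at least 2-fold outside the region. The test covers genes inside the region, so it leaves open the 272 lower genes outside it.

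Liver-type transcripts such as Alb, Ahsg and Apoa2 were far higher on the kidney control and low arrays than on the intermediate and high arrays. Neighbouring tissue at dissection, here liver, is a candidate that stays open. Markers of other tissues that adjoin the kidney also differed between kidney arrays in an order other than that of the levels, by a median range of 3.95 for adrenal gland (Star, Chga, Hsd3b1), 3.19 for pancreas (Prss3) and 2.56 for brown fat (Ucp1). Lower renal transcript levels with infection were predicted to bear no relation to liver abundance. The r across 437 genes with the liver control array was 0.34 higher for kidney control than for kidney high (0.83 against 0.49), with 329 of these genes above background on the kidney high array. The 20 brightest alone, a narrower range, showed no such gap (0.43 against 0.51). The 437 genes were selected on these same arrays by liver level over kidney level, which can raise r by itself. A fall in part of them would also lower r on the high array, so this test cannot decide. Liver RNA in the kidney samples followed liver levels at r = 0.83 with a slope of 0.87, yet 17 and not all of the 20 brightest liver-type genes were higher in kidney control than in kidney high, so this stays open. A kidney response in part of these genes also stays open, untested.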

How the results depend on the processing

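The alternatives without the dim region, without genes of other tissues, with the low array as the reference and with the level as a block were chosen after the data were seen, and the others were planned.

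Counts of single genes depended on what was taken as a sample. With each dye channel as a sample and dye as a term, 1008 liver, 122 kidney and 916 joint genes passed, 496 differed between tissues, and 1995 liver and 1359 kidney genes had a trend. Channels of an array are not independent, so these counts come from treating technical spread as spread between samples. Leaving out 1 array gave 0 to 1656 genes in liver (1656 without the low array), 0 to 210 in kidney (210 without the low array), 0 to 14 for the tissue difference (14 without the liver low array) and 0 to 596 for the liver trend (596 without the control array). The joint test and the kidney trend stayed at 0. The liver trend gave 207 genes with the channel median, 123 with no filter on dim probes and 347 with genes above background on all arrays, and the joint test gave 1 with the deposited values. The other alternatives of the limma tests gave 0, among them the liver fit without the dim region (646 at an unadjusted p under 0.05) and the kidney fit without genes of other tissues (327). The cause was not tested.

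The counts of genes changed at least 2-fold moved with the fold limit and with settings that change several steps at once, so no single step can be named for the latter. For liver low, intermediate and high and kidney low, intermediate and high in this order, a 1.5-fold limit gave 2199, 3160, 3100, 627, 2078 and 1887 genes, a 3-fold limit 749, 1084, 1101, 95, 445 and 385, and the deposited values, which keep the background and have no dye normalisation, 807, 1115, 1022, 90, 606 and 463. Limma with channels as replicates called 4184, 4555, 4565, 1939, 4424 and 4030. Normexp with loess and Aquantile, which started from median signals because mean spot signals were not used here, gave 73, 481 and 355 in kidney. With no filter 3221 genes were counted at liver intermediate. The dim region left out gave 592 genes at liver low, of which 487 were shared with the 1371 counted before. Against the low array, 935 genes were counted at liver intermediate and 1066 at liver high. Without genes of other tissues the kidney counts were 173, 856 and 724.

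The share of higher genes also moved with scaling. It was 42.0% at liver low and 63.2% with the channel median, 47.7% at liver intermediate and 62.4%, and with normexp 59.1% at liver intermediate and 51.5% against 63.9% at kidney high. The median change of all liver genes at low, intermediate and high was 0.16, -0.17 and -0.10, and 0.56, 0.10 and 0.01 with the channel median.

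Of 32 lists, camera called 21 in liver and 22 in kidney. With an estimated correlation 0 and 0 were called (smallest adjusted p = 0.56 and 0.65), and the directional test of fry called 0 and 0 (0.34 and 0.36), with 3 lists in each tissue at an unadjusted p under 0.05. The mixed test of fry, which takes changes in either direction, called 2 lists in liver and 0 in kidney. The 2 were acute phase proteins (adjusted p = 0.02) and inflammatory cytokines and chemokines (0.05 after rounding). Leaving out 1 array gave 20 to 23 lists in liver and 18 to 23 in kidney. The calls of erythroid (adjusted p = 0.0506) and oxidative phosphorylation genes (0.0679) in liver and of fatty acid oxidation (0.1835) and apoptosis genes (0.0688) in kidney ended with the deposited values, and those of oxidative phosphorylation in liver (0.0730) and apoptosis in kidney (0.0604) with no filter. The apoptosis call in kidney also ended without genes of other tissues (0.0608), with the same 28 members and median of 0.19, so the list itself had not changed. Without genes of other tissues, camera called acute phase proteins (adjusted p = 0.0024 over 6 genes) and complement and coagulation genes (0.0024 over 19 genes) higher in kidney, and without the dim region it called fatty acid oxidation genes lower in liver (0.0385). The filter behind the kidney calls used the infected kidney arrays and favoured rising genes, so those calls are no independent check. The direction of the test reversed for no called list, and that of the change for no named gene, under the alternatives run, although the median of female-biased genes in kidney was 0.03 without genes of other tissues.

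By replicate number, no paired analysis was possible because each group held replicate 1 alone. The labels do not say that the liver and kidney of a level came from the same mice. With the parasitaemia level as a block, limma called 0 genes for the tissue difference (smallest adjusted p = 0.49), with 659 at an unadjusted p under 0.05. Signal over background was lower in liver, 5.62 to 10.63 times at the 75th percentile, than in kidney, 18.02 to 28.35 times, which left fewer liver genes to test.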

Other observations

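The markers of red cell precursors, adrenal gland, pancreas, brown fat and muscle, and the tests below that use them, were chosen after the results were seen, while the erythroid list was planned.

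Transcripts of red cell precursors were far higher on the liver intermediate and high arrays. Slc4a1, the anion exchanger of red cells, read 2.45 and 3.86 there against -0.71 on the control array, and of 16 precursor markers 15 were well above background on each of these arrays, against 5 on the control and 1 on the low array. Their detection was not particular to liver, with 10, 9, 12 and 15 above background on the kidney arrays from control to high. Signal over background was lower in liver, so counts are not directly comparable between tissues. Erythroid precursor cells in liver, where adult mice can form red cells during anaemia, are a candidate source: precursor markers had a median change of 3.81 at high parasitaemia, but globins and haem synthesis genes had 0.97, short of the 1 log2 asked for, and at intermediate parasitaemia the medians were 3.15 and -0.04. Red cells in the blood of both organs could not be told apart from this, since the median change of precursor markers in kidney was 1.89 at high parasitaemia, or 0.50 of that in liver, although at intermediate it was 0.78 against 3.15, and globins and haem synthesis genes in kidney had -0.82 at intermediate and -0.10 at high. A general rise of all dividing cells stayed open as well, as the ratio of the precursor to the cell cycle change was 0.02 higher in liver than in kidney at high and 0.72 higher at intermediate parasitaemia.

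Gata1, the master regulator of red cell formation, was well above background in both channels of the liver intermediate and high arrays and in 1 channel of the kidney high array. Globin genes were high on every array: Hbb-bt, a beta globin, read 6.83 on the liver control and 7.21 on the liver high array, and 5.75 and 5.96 on the corresponding kidney arrays.

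Xist, which is transcribed from the inactive X chromosome, read 3.32 to 4.21 on the 8 arrays and was well above background on each. The Y-linked genes Kdm5d and Uty were below that limit on every array apart from 1 channel of liver high for Kdm5d.

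Of 12 skeletal muscle markers, Acta1, Tnni2 and Tnnc2 were well above background in both channels of the liver low array, Tnni2 and Cox6a2 in those of the intermediate and Cox6a2 in those of the high array, and no marker in those of the control array. The medians of the list, -4.83 on the liver control, -2.87 on the low, -5.86 on the intermediate and -5.03 on the high array, were mostly made of readings near background, which differs between arrays.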
